A study of Mus musculus with 88 samples.

How the data were processed

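Total RNA from mouse cells and embryos was made into stranded libraries with a SMART-seq kit from Takara and sequenced, per the labels' protocols. The series lists 88 samples. The 25 libraries analysed here stood in 2 tables of transcript abundance, 1 for mouse embryonic stem cells (mESCs, 19 libraries) and 1 for late 2-cell embryos (6 libraries). The other 63 samples, among them labelled nascent RNA, chromatin profiles, embryos injected with siRNA against Obox3 and embryos treated with inhibitors, were not analysed here.

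The deposited values are TPM per gene, per the file headers, a unit of transcript abundance that scales reads by gene length and by the library's total. Each column summed to 1000000. The submitters' processing notes name HISAT2, Trim Galore, featureCounts 1.6.5, bedtools, deepTools, Bowtie2, MACS2 and mm10, without saying which tool made which values. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as the Obox, Zscan4, Tcstv, Trim43, Usp17l and Dux families, and genes that overlap others, such as microRNAs inside longer transcripts, are therefore uncertain in level. Each table held 55364 genes under Ensembl identifiers with symbols. Of these identifiers 54312 were also in the table of gene names used here, and 217 symbols stood for more than 1 gene. Coordinates were taken from RefSeq on GRCm38.p6, a patch of the mm10 assembly. The mESC and embryo tables were normalised separately, so tests were run within a table only.

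Groups came from the sample labels. Columns were matched to samples by name. For 3 mESC columns, 1 each of ES_Dux, ES_Obox3 and ES_Obox5, the name gave the group and a replicate number that the labels of the group do not have. These were used as members of their group only and are called the unnumbered library of the group. All of them carry the number 3, which no ES_Empty or ES_Obox6 library has. Whether they were made together, apart from the other libraries, is not known. Every replicated group had 2 libraries. Nothing in the labels ties the replicates to separate cultures or separate collections of embryos, so p-values measure only the spread between these samples, which may be technical. The libraries of a group had correlations across genes of log2(TPM + 1) from 0.935 to 0.953 in mESCs and from 0.944 to 0.949 in embryos, and no pair held identical values.

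TPM keep no sequencing depth. Where the authors counted whole reads, the low values of genes of a known length are multiples of what 1 read is worth, and 3138 short genes were used to look for that step. It put 1 read on a 1-kb gene at 0.136 to 0.441 TPM in the mESC libraries and at 0.0718 to 0.198 TPM in the embryo libraries. With a tolerance of 1e-05, 52.7 to 61.7% of these genes' values in mESCs and 56.7 to 60.6% in embryos were whole reads, and a further 17.1 to 21.4% and 17.7 to 21.4% lay midway between whole reads. Counts were not recovered for all genes, and no count model was used. A 1-kb gene at 1 TPM rested on 2.27 to 7.37 reads in mESCs and on 5.06 to 13.9 reads in embryos, so differences among genes near 1 TPM rest on few reads. At the same TPM a shorter gene, such as a microRNA gene, rests on fewer reads. The 10 most abundant genes, mostly small noncoding RNAs such as Rpph1, Rn7sk, Rn7s2 and Rmrp, took 48.7 to 73.8% of the TPM in the mESC libraries and 57.4 to 72.6% in the embryo libraries. Because TPM sum to a constant, a gain in such genes lowers the TPM of all others.

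Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(TPM + 1), with a variance trend, robust moderation and Benjamini-Hochberg adjustment. Genes had to reach 1 TPM in at least 2 of the libraries fitted. All groups of a table shared 1 estimate of the spread, over 10 mESC libraries (5 residual degrees of freedom, 3.71 prior degrees of freedom) or 6 embryo libraries (3 and 3.48). A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. A group whose libraries were all without value is described as listed at 0, with no fold change.

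Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Adjustment ran over the lists of a comparison. A list's relative median is the median log2 fold change of its members minus that of all genes tested. Of 19 fixed lists, 18 had enough measured members in mESCs and 17 in embryos. A list of 13 mitochondrially encoded genes had 0 members in the tables. The lists share a few genes, such as Hand1 and Otx2. The groups, the comparisons, the tests, the thresholds, the lists, the rule for named genes and most alternative settings were chosen before the data were examined.

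Named genes were the expressed or injected gene; the 6 largest increases and 6 largest decreases among called genes whose libraries did not overlap, with a mean of at least 5 TPM in the higher group and a symbol that was not a provisional or pseudogene name; the 3 members of each list with the smallest p; and Zscan4c, Zscan4d, Tcstv3, Zfp352, Dux, Duxf3, Pou5f1, Nanog, Sox2, Cdkn1a, Xist and Kdm4d where the table held them. The symbol Dux was not in the tables, and Duxf3 was used in its place.

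Overlaps between comparisons that share control libraries were set beside 50 simulations of unchanged groups and beside the overlap of independent lists. In the simulations the controls were drawn anew, with noise independent between genes. With 2 control libraries, the controls were not split. Single libraries were compared with the ES_Empty mean without a test, and list medians were placed among 10000 random lists of the same size matched on mean expression. The steps were tested on simulated data in which 200 genes were changed. For ES_Obox3 against ES_Empty (17534 genes), 67.2% of genes changed 2.5-fold, 95.5% of those changed 4-fold and 97% of those changed 8-fold were recovered, 7% of calls were false, and 0 of 100 unchanged lists passed. For control transfer embryos against injected-sperm embryos (16644 genes), the shares were 64.2, 92.5 and 97%, 8.6% of calls were false, and 2 of 100 unchanged lists passed, 0 with an estimated correlation. The simulated genes varied independently, so these lists do not show how camera at the preset correlation treats correlated genes. The estimated correlation was 0.826 for proteasome subunits in mESCs.

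The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-ratio scaling, quantile normalization, a fit of only the groups compared, the replicate number as a block, plain moderation, no minimum fold change, an estimated correlation, and leaving out each library in turn. Rescaling without the 10 most abundant genes and a fit of protein-coding genes alone, and median-ratio scaling together with an estimated correlation, were added after the data were seen. Data were prepared and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.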

Results

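Obox genes encode homeodomain proteins made in oocytes and early mouse embryos, and Obox3 is among those transcribed when the embryonic genome is activated. The libraries analysed here measured total RNA in 2 settings. In the first, male mESCs grown with LIF and inhibitors of MEK and GSK3 were transfected with plasmids for single homeobox genes. Groups of 2 libraries carried an empty plasmid (ES_Empty), Dux (ES_Dux), Obox3 (ES_Obox3), Obox5 (ES_Obox5) or Obox6 (ES_Obox6), and 9 single libraries carried Obox1, Obox2, Obox4-ps27, Obox4-ps35, Obox7, Obox8 or 1 of 3 Crxos constructs. In the second setting, late 2-cell embryos were made by somatic cell nuclear transfer (SCNT), in which a cumulus cell nucleus is placed in an enucleated oocyte, and injected with 10 ng/µl of Obox3 mRNA (SCNT_Obox3_L2C) or of EGFP mRNA (SCNT_EGFP_L2C). Embryos made by intracytoplasmic sperm injection (ICSI_L2C) were the fertilised reference, and each of these 3 groups had 2 libraries. Between 12071 and 17597 genes reached 1 TPM in an mESC library, and between 15604 and 16450 in an embryo library. Values are TPM as mean ± SD with n = 2 per group, and log2 fold changes are given with the standard error (SE) and the adjusted p of limma.

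The expressed genes were found in the libraries that carry their names. Duxf3, the Dux gene of the tables, stood at 1548 and 1979 TPM in the ES_Dux libraries, Obox5 at 971 and 933 TPM in ES_Obox5, and Obox6 at 2031 and 1959 TPM in ES_Obox6. Both Obox5 and Obox6 were listed at 0 in ES_Empty. In ES_Obox3 the Obox3 gene itself (chromosome 7, 15625306 to 15639777, protein coding) was near the floor, at 1.75 and 1.59 TPM, and its call against ES_Empty was lost without ES_Empty replicate 1 (adjusted p = 0.0908) or replicate 2 (adjusted p = 0.0726). The near-identical copy Obox3-ps5, chosen after its values were seen, stood at 450.7 and 262.8 TPM in ES_Obox3 and was listed at 0 in ES_Empty, so the level of the Obox3 plasmid is uncertain between these copies. Among the single libraries, the expressed gene stood at 1725 TPM for Obox1, 1450 for Obox2, 1711 for Obox4-ps27, 8450 for Obox4-ps35, 3348 for Obox7 and 2465 for Obox8, and Crxos stood at 2819, 1244 and 1458 TPM with its 3 constructs.

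ES_Obox3 was compared with ES_Empty to ask which genes Obox3 changes in stem cells. Trim43a (chromosome 9, 88580891 to 88588824), of a gene family transcribed at the 2-cell stage, stood at 87.0 ± 24.0 TPM against 0.0677 ± 0.0957 (log2 fold change 6.34, SE 0.221, adjusted p = 4.18e-06). Dppa3 (chromosome 6, 122626424 to 122630271), a maternal factor that limits DNA demethylation in the zygote, rose from 2.69 ± 0.879 to 229.6 ± 43.5 TPM (5.97, SE 0.327, adjusted p = 3.23e-05). Klf17 (chromosome 4, 117756659 to 117765666), a Krüppel-like transcription factor, rose from 0.112 ± 0.158 to 48.5 ± 13.0 TPM (5.46, SE 0.354, adjusted p = 6.6e-05). Guca1a rose from 0.213 ± 0.134 to 79.2 ± 16.2 TPM (6.04, SE 0.225, adjusted p = 5.59e-06), and Naalad2 and Pemt rose by log2 fold changes of 5.59 (SE 0.349) and 5.33 (SE 0.236). The stem cell factor Sox2 (chromosome 3, 34649995 to 34652461) fell from 72.4 ± 8.6 to 12.1 ± 3.28 TPM (-2.50, SE 0.261, adjusted p = 0.00043). Among the largest decreases were Nkx6-2, a homeobox gene, at -3.76 (SE 0.237, adjusted p = 5.94e-05), Lrrc34 at -3.59 (SE 0.29, adjusted p = 0.000168), and the microRNA genes Mir3070b, Mir494 and Mir411, at 25.5, 19.4 and 18.2 TPM in ES_Empty and listed at 0 in ES_Obox3. On a 1-kb gene 1 read was worth 0.269 and 0.205 TPM in the ES_Empty libraries. It is worth more on a short microRNA gene, so these 3 decreases may rest on few reads.

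Of 47 measured 2-cell-stage genes, 21 were called higher and 0 lower in ES_Obox3 (22 and 0 adjusted over the list alone), with a relative median of 1.27. For every list of this comparison other than this and the oocyte genes, the counts adjusted over the list alone were those over all genes. The list's adjusted p was 1.54e-21, and adjusted p = 0.0651 with an estimated correlation (adjusted p = 0.0066 with that correlation after median-ratio scaling). Besides Trim43a these members included Pramel7 (4.84, SE 0.293, adjusted p = 5.25e-05) and Chit1, a chitinase at 29.2 ± 7.01 TPM that was listed at 0 in ES_Empty (adjusted p = 9.64e-06). The members most used as markers of the 2-cell-like state did not pass: Zscan4d had a log2 fold change of 0.14 (adjusted p = 0.703), Zscan4c -0.53 (0.353), Zfp352 0.60 (0.0944) and Tcstv3 0.85 (0.104). Among Obox and related homeobox genes, 4 of 8 were called higher (relative median 1.25, adjusted p = 8.6e-05, and adjusted p = 0.0651 with an estimated correlation). They were Obox3, Obox8, Crx and Crxos, a homeobox gene neighbouring Crx that rose from 0.662 ± 0.422 to 29.1 ± 7.05 TPM (4.18, SE 0.295, adjusted p = 9.15e-05). Obox8 was near the floor, at 1.61 and 1.39 TPM, and was listed at 0 in ES_Empty.

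Of 30 naive pluripotency genes, 16 were called lower and 1 higher, against 10 and 2 after scaling (relative median -0.64, adjusted p = 0.000481, and adjusted p = 0.811 with an estimated correlation; adjusted p = 0.0299 with that correlation after scaling). Nr0b1, a nuclear receptor of naive cells, fell by 2.00 (SE 0.205, adjusted p = 0.000404) and Spp1 fell by 2.55 (SE 0.244, adjusted p = 0.000307). Fbxo15 went the other way, from 28.2 ± 3.15 to 210.6 ± 44.5 TPM (2.84, SE 0.201, adjusted p = 9.15e-05). Pou5f1 was called lower at -1.04 (SE 0.191, adjusted p = 0.0053), but stood at -0.46 and uncalled after median-ratio scaling, at -0.94 without ES_Empty replicate 1 and at -0.85 without the unnumbered ES_Obox3 library. Nanog had a log2 fold change of -0.96 (SE 0.234, adjusted p = 0.0168) and was not called.

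Of 6 early lineage genes, 3 were called higher and 1 lower (relative median 0.79, adjusted p = 0.0202, and adjusted p = 0.703 with an estimated correlation; adjusted p = 0.0524 without the unnumbered ES_Obox3 library and 0.134 after scaling). Gata4, a transcription factor of primitive endoderm and heart, rose from 0.435 ± 0.128 to 19.9 ± 7.27 TPM (3.82, SE 0.267, adjusted p = 9.15e-05), and Hand1, listed at 0 in ES_Empty, reached 3.26 ± 0.864 TPM (adjusted p = 0.000818). Of 11 oocyte genes, 3 were called higher and 2 lower (4 and 2 adjusted over the list alone; relative median 0.97, adjusted p = 0.0056, and adjusted p = 0.703 with an estimated correlation). Padi6, a component of oocyte lattices, rose by 1.61 (SE 0.27, adjusted p = 0.00359), and Nlrp4f fell by 2.43 (SE 0.235, adjusted p = 0.000322). Among 14 cumulus and granulosa cell genes, 5 were called lower, including Vcan and Vim at -2.16 and -2.35 (adjusted p = 0.022, and adjusted p = 0.738 with an estimated correlation; adjusted p = 0.0512 without the unnumbered ES_Obox3 library). Among 11 Xist and H3K27me3-imprinted genes, 5 were called lower, of which 1 was called after scaling (adjusted p = 0.0056, and adjusted p = 0.703 with an estimated correlation). Slc38a4, an imprinted amino acid transporter, stood at -1.56 (SE 0.271, adjusted p = 0.00416).

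Other lists moved in both directions or little. Krt18, a keratin of trophoblast, rose by 2.76 (SE 0.262) while Eomes, a T-box factor of the same list, fell by 2.71 (SE 0.296). Within the chromatin modifiers, the DNA methyltransferase Dnmt3a rose by 1.49 (SE 0.231, adjusted p = 0.00249) and the demethylation enzyme Tet2 fell by 1.83 (SE 0.245, adjusted p = 0.0013), with 1 higher and 6 lower calls among 33, against 3 and 1 after scaling. Stress and immediate early genes had 3 higher and 4 lower calls among 16 (4 and 3 after scaling), with Gadd45a and Junb at -2.62 and -2.52. The DNA replication list had 1 higher and 3 lower calls among 35 (2 and 0 after scaling), the interferon response list 2 lower among 7 (1 higher and 1 lower after scaling), and the fibroblast list 1 lower among 5. None of these lists passed camera, nor did the trophoblast list. For p53 targets (0 higher and 5 lower of 18, 0 and 1 after scaling, adjusted p = 0.0202), proteasome subunits (0 and 0 of 31, adjusted p = 0.0206), splicing factors (0 and 2 of 44, 1 and 0 after scaling, adjusted p = 0.0202) and ribosomal proteins (0 and 0 of 87, adjusted p = 0.00674), every call of the list was lost with an estimated correlation (adjusted p = 0.811, 0.837, 0.837 and 0.837). They were also lost without ES_Empty replicate 1 (adjusted p = 0.0596, 0.252, 0.252 and 0.252) without the unnumbered ES_Obox3 library (adjusted p = 0.0512, 0.0905, 0.103 and 0.0704) and after scaling (adjusted p = 0.484, 0.827, 0.827 and 0.0699). Ribosome biogenesis genes had 1 lower call among 54 (adjusted p = 0.843), and after scaling 5 higher and 0 lower (adjusted p = 0.000984, and adjusted p = 0.307 with an estimated correlation). Their relative median, 0.08, and their test, downward, differed in sign, as did those of the trophoblast list.

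In all, limma called 951 genes higher and 2770 lower in ES_Obox3, or 25.6% higher. The median of all genes was -0.42, and median-ratio scaling moved that shift to 0 and turned the split to 1485 higher and 835 lower, or 64% higher. Under both, 933 genes were called higher and 835 lower. Without ES_Empty replicate 1 the calls numbered 664 higher and 1570 lower.

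**Figure D1:**
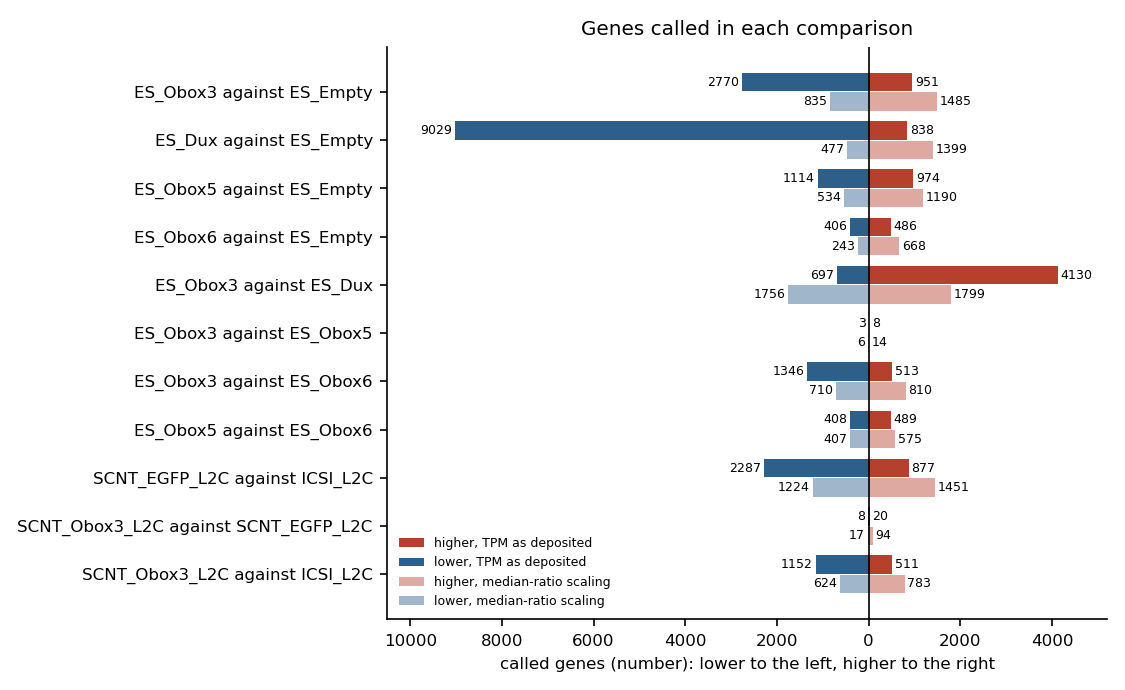
Numbers of genes called higher and lower by limma (x axis, genes) in each of the 11 comparisons (y axis), from TPM as deposited and after median-ratio scaling. ES_Obox3 against ES_Empty goes from 951 higher and 2770 lower to 1485 higher and 835 lower, and ES_Dux from 838 and 9029 to 1399 and 477.

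Dux, a pioneer transcription factor of the 2-cell stage, was expressed as a reference for the 2-cell-like state. In ES_Dux against ES_Empty, Zscan4d (chromosome 7, 11161643 to 11166148), a gene transcribed in 2-cell embryos, rose from 0.0521 ± 0.00988 to 1135 ± 138 TPM (10.07, SE 0.249, adjusted p = 1.6e-07). Zscan4c rose from 0.842 ± 1.06 to 539 ± 22.4 TPM (8.33, SE 0.409, adjusted p = 6.89e-06), and AW822073 from 0.105 to 2882 ± 261 TPM (11.35, SE 0.325, adjusted p = 2.33e-07). Tcstv3 reached 201.6 ± 26.4 TPM and was listed at 0 in ES_Empty (adjusted p = 3.44e-06), and Zfp352 rose by 4.21 (SE 0.248, adjusted p = 1.48e-05). Of the 47 2-cell-stage genes 40 were called higher and 1 lower, Duxf3 included (relative median 6.46, adjusted p = 2.06e-83, and adjusted p = 0.00404 with an estimated correlation). Obox4-ps27 was listed at 0 in ES_Empty and reached 9.76 TPM (adjusted p = 7.65e-05). With Obox4-ps35 it made up the 2 higher calls among Obox and related homeobox genes (relative median 1.37, adjusted p = 1.31e-06, and adjusted p = 0.0315 with an estimated correlation).

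Growth factor and transcription factor genes of naive stem cells fell. Fgf4 fell from 69.1 ± 4.57 to 7.41 ± 0.646 TPM (-3.06, SE 0.168, adjusted p = 9.52e-06), Tbx3 fell by 2.55 (SE 0.21, adjusted p = 0.000116), Klf4 fell by 2.41 (SE 0.194, adjusted p = 0.000105) and Sox2 fell by 2.70 (SE 0.261, adjusted p = 0.000201). Of 30 naive pluripotency genes 26 were called lower, against 8 lower and 1 higher after scaling (relative median -0.80, adjusted p = 1.12e-05, and adjusted p = 0.725 with an estimated correlation; adjusted p = 0.0358 with that correlation after scaling). Nanog was called at -2.25 (SE 0.234, adjusted p = 0.000242) and stood at -0.85 and uncalled after scaling. Pou5f1 was not called, at -0.86 as deposited and 0.56 after scaling. The stress genes Junb and Trib3 fell by 3.05 and 2.61 and the demethylation enzymes Tet2 and Tet1 fell by 2.57 and 2.41. The list of stress and immediate early genes had 10 lower calls among 16, or 2 after scaling, and did not pass camera (adjusted p = 0.184).

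Other lists changed with the scale of the table. In this comparison the counts adjusted over the list alone equalled those over all genes for every list. Lower calls covered 49 of the ribosome biogenesis genes, 34 of the DNA replication genes, 28 of the chromatin modifiers, 32 of the splicing factors and 15 of the p53 targets, and after scaling 0, 1, 2, 0 and 0 were left. All of these lists passed camera as deposited, with adjusted p = 5.85e-05, 7.31e-05, 7.31e-05, 0.00136 and 0.0117, and had adjusted p = 0.725 with an estimated correlation. After scaling the ribosome biogenesis, DNA replication and p53 target lists no longer passed (adjusted p = 0.357, 0.358 and 0.0688). Chromatin modifiers still passed downward (adjusted p = 0.00466) and splicing factors passed upward (adjusted p = 0.0114), both lost with an estimated correlation (adjusted p = 0.137 and 0.409). Proteasome subunits (11 lower, adjusted p = 0.0276) had a relative median and a test of opposite sign and a higher direction after scaling (adjusted p = 4.31e-10). With an estimated correlation neither call held (adjusted p = 0.725 as deposited and adjusted p = 0.081 after scaling). The call as deposited was also lost without ES_Empty replicate 1 (adjusted p = 0.156), either ES_Dux library (0.0729 and 0.1) or either ES_Obox5 library (0.0735 and 0.0627). The list of Xist and H3K27me3-imprinted genes had 10 lower calls, 1 after scaling (adjusted p = 0.037, and adjusted p = 0.725 with an estimated correlation; adjusted p = 0.0551 without ES_Empty replicate 2, 0.0546 without the unnumbered ES_Dux library, 0.0531 and 0.0509 without either ES_Obox6 library, and 0.0598 after scaling). Ribosomal proteins (7 lower, adjusted p = 0.259) had 8 higher calls and 0 lower after scaling.

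In all, 838 genes were called higher and 9029 lower in ES_Dux, or 8.5% higher, with a median of all genes of -0.97. After median-ratio scaling the calls were 1399 higher and 477 lower, or 74.6% higher.

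**Figure D2:**
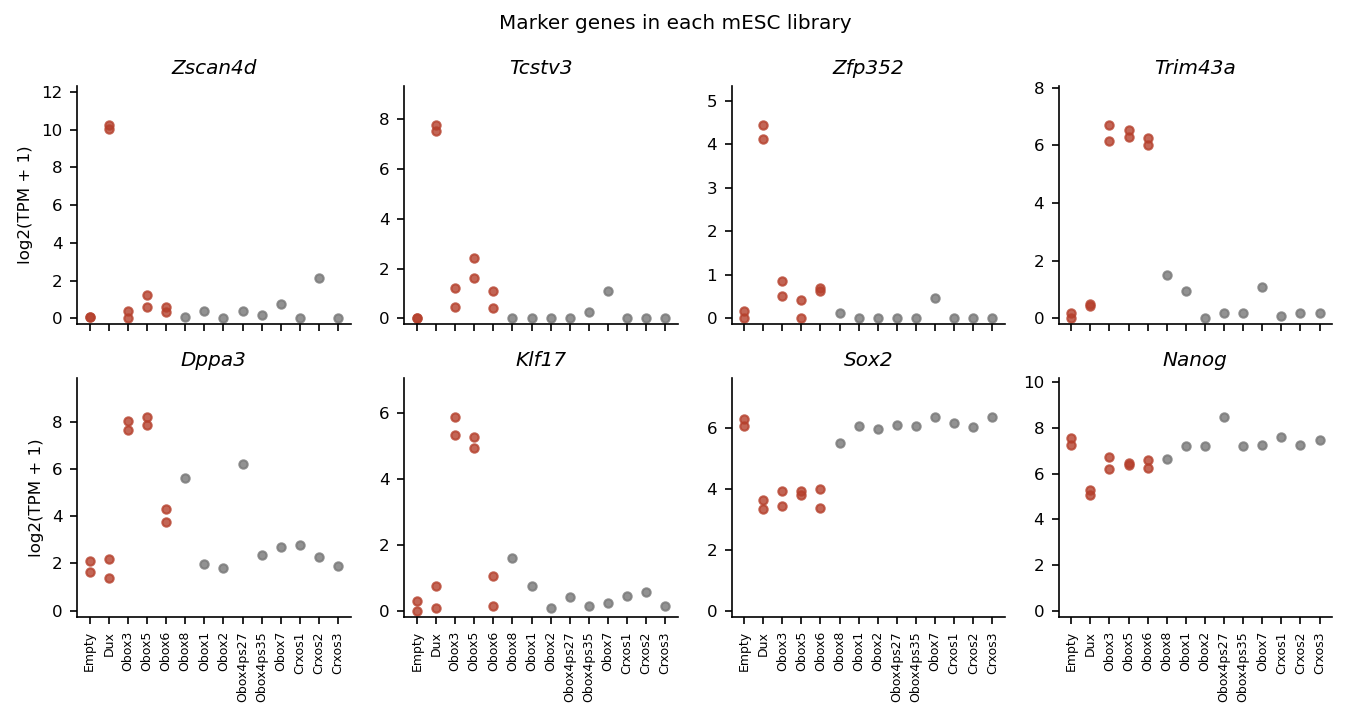
Log2(TPM + 1) (y axis) of Zscan4d, Tcstv3, Zfp352, Trim43a, Dppa3, Klf17, Sox2 and Nanog in each of the 19 mESC libraries (x axis); red points are libraries of replicated groups and grey points single libraries. Zscan4d stands near 1135 TPM in ES_Dux against 0.0521 TPM in ES_Empty, while Dppa3 and Klf17 are high in ES_Obox3 and ES_Obox5.

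ES_Obox5 and ES_Obox6 were compared with ES_Empty to ask whether other Obox genes change the same genes. In ES_Obox5, Trim43a reached 83.6 ± 9.53 TPM (6.31, SE 0.221, adjusted p = 3.28e-06), Dppa3 reached 259.9 ± 42.6 TPM (6.16, SE 0.327, adjusted p = 2.78e-05) and Gata4 rose by 3.85 (SE 0.267, adjusted p = 0.000103). Bex6 stood at 48.0 ± 2.02 TPM and was listed at 0 in ES_Empty. Sox2 fell by 2.32 (SE 0.261, adjusted p = 0.000951), Cldn4 fell by 3.09 (SE 0.299, adjusted p = 0.000521) and Klf4 fell by 1.87 (SE 0.194, adjusted p = 0.000655). Nanog at -0.98, Pou5f1 at -0.77 and Zscan4d at 0.84 were not called. Of the 2-cell-stage genes 25 were called higher and 0 lower (27 and 0 adjusted over the list alone; relative median 1.45, adjusted p = 5.3e-24, and adjusted p = 0.0609 with an estimated correlation; adjusted p = 0.00288 with that correlation after scaling). Naive pluripotency genes had 1 higher and 9 lower calls (1 and 10 over the list alone), against 3 and 6 after scaling, with adjusted p = 0.00199, and adjusted p = 0.91 with an estimated correlation (adjusted p = 0.0461 with that correlation after scaling). Oocyte genes had 3 higher and 1 lower calls (4 and 1 over the list alone; adjusted p = 0.00734, and adjusted p = 0.774 with an estimated correlation; adjusted p = 0.0503 without the unnumbered ES_Obox5 library). The early lineage list had 3 higher and 0 lower calls (3 and 1 over the list alone; adjusted p = 0.0274, and adjusted p = 0.774 with an estimated correlation; adjusted p = 0.0571 without that library and 0.0757 after scaling). Of the homeobox genes 3 were called higher, Obox5 included (adjusted p = 6.14e-05, and adjusted p = 0.0609 with an estimated correlation). The Xist and H3K27me3-imprinted list had 2 lower calls, or 0 after scaling (adjusted p = 0.0253, and adjusted p = 0.832 with an estimated correlation). It did not pass without the unnumbered ES_Obox5 library. In all, 974 genes were called higher and 1114 lower, or 46.6% higher, and 1190 and 534, or 69% higher, after scaling, which moved the median of all genes from -0.20 to 0. The count fell to 1074 without ES_Empty replicate 1, 1237 without replicate 2, 1111 without ES_Obox5 replicate 1 and 1155 without the unnumbered ES_Obox5 library.

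In ES_Obox6, Trim43a reached 69.2 ± 7.84 TPM (6.04, SE 0.221, adjusted p = 6.38e-06) and Pdpn, a membrane glycoprotein gene, rose from 4.98 ± 0.49 to 136.9 ± 10.0 TPM (4.53, SE 0.18, adjusted p = 9.69e-06). The transcription factor genes Sox7, Gata6 and Gata4 and the collagen gene Col4a1 rose, with Sox7 at 2.25 (SE 0.261, adjusted p = 0.00242), Gata6 at 1.98 (SE 0.23, adjusted p = 0.00242), Gata4 at 1.92 (SE 0.267, adjusted p = 0.00497) and Col4a1 at 2.46. The early lineage list had 4 higher and 0 lower calls among 6 (4 and 1 over the list alone; relative median 1.67, adjusted p = 4.72e-05, and adjusted p = 0.196 with an estimated correlation). Dnmt3a rose by 3.27 (SE 0.231, adjusted p = 0.000322), Sox2 fell by 2.51 (SE 0.261, adjusted p = 0.00152), and Sall1 and Dnmt3l fell by 2.77 and 2.61. Dppa3 rose by 2.16 (SE 0.327, adjusted p = 0.00702), a call lost without ES_Empty replicate 2 (adjusted p = 0.0535). Nanog at -0.98 and Pou5f1 at -0.67 were not called. The 2-cell-stage list had 9 higher calls and 0 lower (14 and 0 over the list alone; relative median 0.64, adjusted p = 9.41e-12, and adjusted p = 0.158 with an estimated correlation; adjusted p = 0.0112 with that correlation after scaling), and the naive pluripotency list 1 higher and 12 lower (adjusted p = 8.2e-10, and adjusted p = 0.85 with an estimated correlation; adjusted p = 0.00777 with that correlation after scaling). The homeobox list had 2 higher calls, the transgene Obox6 included (median 0.24, mean 1.81, adjusted p = 0.000775, and adjusted p = 0.158 with an estimated correlation). Its test thus rests in part on the transgene itself. Ribosome biogenesis genes, splicing factors, ribosomal proteins and proteasome subunits passed downward with 0 called members (adjusted p = 1.09e-05, 1.09e-05, 1.07e-05 and 0.00438), as did DNA replication genes with 1 lower call (adjusted p = 0.000653), each with adjusted p = 0.85 with an estimated correlation. The proteasome call was lost without ES_Empty replicate 1 (adjusted p = 0.241) or ES_Obox6 replicate 2 (adjusted p = 0.125), and after scaling (adjusted p = 0.166). In all, 486 genes were called higher and 406 lower, or 54.5% higher, and 668 and 243, or 73.3% higher, after scaling, which shifted all genes by 0.19. The count fell to 325 without ES_Empty replicate 1, 397 without replicate 2, 400 without ES_Obox6 replicate 1 and 399 without replicate 2.

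**Figure D3:**
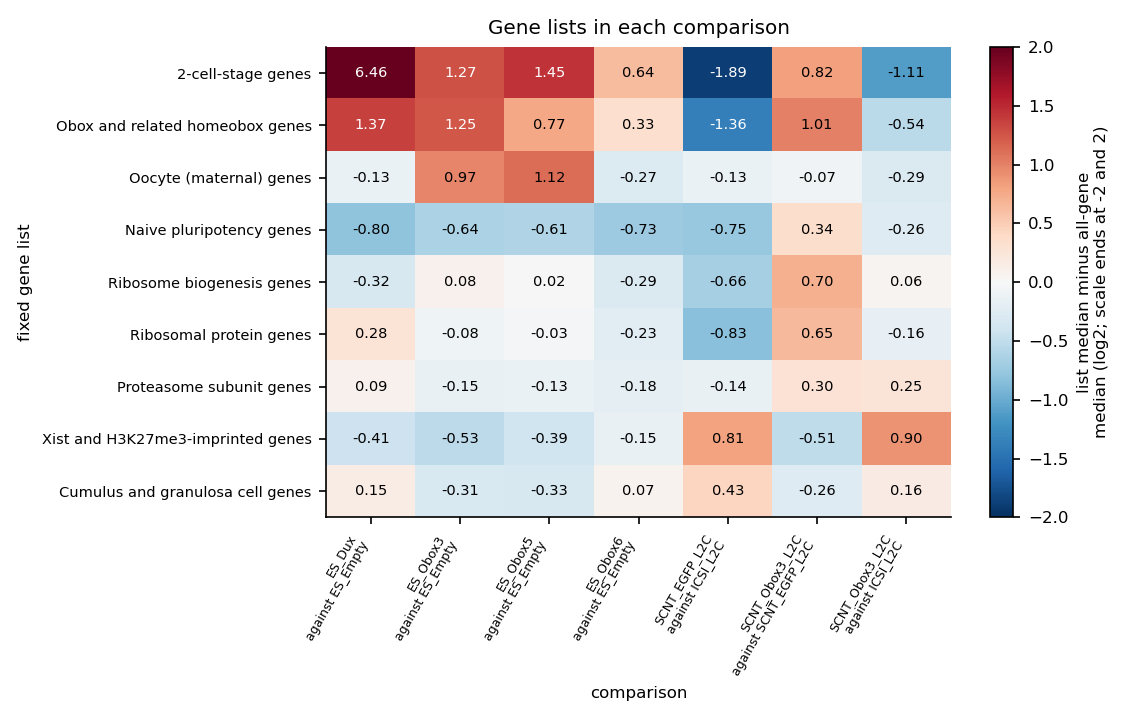
Relative median log2 fold change of 9 gene lists (y axis) in 7 comparisons (x axis), drawn as colour from lower to higher than the median of all genes. The 2-cell-stage list runs from 6.46 in ES_Dux against ES_Empty to -1.89 in SCNT_EGFP_L2C against ICSI_L2C.

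The responses were then set side by side. Of the 951 genes higher in ES_Obox3, 698 (73.4%) were also higher in ES_Obox5, 224 in ES_Obox6 and 188 (19.8%) in ES_Dux. Independent lists of these sizes would share 45.5, 22.7 and 39.2 genes. Unchanged groups simulated with shared controls shared at most 1. No gene was changed in them, so few calls could arise and this count does not test the overlap. Across 20355 genes the log2 fold changes of ES_Obox3 and ES_Obox5 had a correlation of 0.843 (simulated 0.5) and a covariance of 0.5937 (simulated 0.0822). For ES_Obox3 and ES_Dux the correlation was 0.477 (simulated 0.5) and the covariance 0.4417 (simulated 0.0824), and after median-ratio scaling the correlation was 0.324 (simulated 0.497) and the covariance 0.2694 (simulated 0.0727). Genes are not independent replicates, and part of each excess may come from the shared ES_Empty libraries, which were not split because each part would hold 1 library. ES_Obox3 and ES_Dux shared 2238 lower calls (1228.7 if independent), against 142 (19.6 if independent) after scaling, and 166 genes were called in opposite directions, or 13 after scaling. The shared higher calls numbered 285 after scaling, 118 without ES_Empty replicate 1 and 124 without replicate 2. The shared lower calls numbered 1326 without ES_Empty replicate 1, 3416 without ES_Obox3 replicate 1 and 1276 without the unnumbered ES_Obox3 library.

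Tested against each other directly, ES_Obox3 exceeded ES_Dux in Dppa3 (6.05, SE 0.327, adjusted p = 7.89e-06), Trim43a (5.96, SE 0.221, adjusted p = 9.33e-07) and Klf17 (5.20, SE 0.354, adjusted p = 2.87e-05). It was lower in AW822073 (-10.16, SE 0.325, adjusted p = 5.49e-07), Zscan4d (-9.93, SE 0.249, adjusted p = 1.95e-07), Tcstv3 (-6.81) and Zfp352 (-3.60). Sox2 did not differ detectably (0.20, adjusted p = 0.608). Of the 2-cell-stage genes 34 were called lower and 5 higher in ES_Obox3 than in ES_Dux (relative median -4.22, adjusted p = 1.05e-40, and adjusted p = 0.0222 with an estimated correlation). In all, 4130 genes were called higher and 697 lower (85.6% higher), and 1799 and 1756 (50.6% higher) after scaling, which moved the median of all genes from 0.48 to 0. Without ES_Obox3 replicate 1 the count was 3180.

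ES_Obox3 and ES_Obox5 differed in few genes. Limma called 8 genes higher and 3 lower in ES_Obox3, with 2231 genes at an unadjusted p under 0.05. Mir3475, a short microRNA gene whose level may rest on few reads, stood at 9.86 ± 3.76 TPM and was listed at 0 in ES_Obox5 (adjusted p = 0.0076). Its call was lost without either ES_Obox5 library. Gsc2, a homeobox gene, stood at 15.9 ± 0.436 against 3.16 ± 0.183 TPM (2.02, SE 0.248, adjusted p = 0.0459), a call lost without any of 8 libraries, among them the unnumbered ES_Obox3 library (adjusted p = 0.34). The transgene Obox5 differed by -9.57 (SE 0.19, adjusted p = 9.86e-08). The 2-cell-stage list had 0 calls in each direction (adjusted p = 0.596). Naive pluripotency genes (0 calls, and 1 lower over the list alone) and ribosomal proteins (0 calls) passed downward (adjusted p = 0.0115 and 0.0245, and adjusted p = 0.952 for both with an estimated correlation). Both calls were lost without the unnumbered ES_Obox3 library (adjusted p = 0.229 and 0.594), and after scaling (adjusted p = 0.193 for both). The ribosomal call was also lost without any 1 of the libraries of ES_Dux, ES_Obox5 or ES_Obox6 (adjusted p from 0.0514 to 0.353). The count of 11 was 1 without either ES_Obox3 library, 6 without either ES_Obox5 library, 352 when only these groups were fitted and 104 among protein-coding genes, so the data set no firm number of differences.

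Against ES_Obox6, both ES_Obox3 and ES_Obox5 were higher in Klf17 (5.01, SE 0.354, and 4.51, SE 0.354) and Dppa3 (3.81, SE 0.327, and 3.99, SE 0.327), and lower in Trh, the gene of thyrotropin-releasing hormone (-4.52, SE 0.254, and -4.20, SE 0.254). Trh stood at 30.2 ± 7.27 TPM in ES_Obox3 and at a mean of 708.7 TPM in ES_Obox6. Sox7 and Col4a1 were lower in ES_Obox3 than in ES_Obox6 by log2 fold changes of -2.52 and -3.17, and Gata4 was higher by 1.90. The 2-cell-stage list had 10 higher and 0 lower calls in ES_Obox3 against ES_Obox6 (11 and 0 over the list alone; adjusted p = 1.02e-10, and adjusted p = 0.377 with an estimated correlation; adjusted p = 0.0258 with that correlation after scaling) and 10 and 0 in ES_Obox5 against ES_Obox6 (13 and 0; adjusted p = 1.97e-12, and adjusted p = 0.284 with an estimated correlation; adjusted p = 0.00899 with that correlation after scaling). ES_Obox3 against ES_Obox6 gave 513 higher and 1346 lower calls (27.6% higher), and 810 and 710 (53.3% higher) after scaling, with a median of all genes of -0.32 before it. The ribosome biogenesis list passed there with a median of -0.0151 and a mean of 0.1 (adjusted p = 0.000425), and the homeobox list, which holds the transgenes, with a median of 0.59 and a mean of -0.69 (adjusted p = 0.0167), and neither held with an estimated correlation (adjusted p = 0.991 and 0.392). The homeobox call was lost without either ES_Obox3 library (adjusted p = 0.153 and 0.822) and after scaling (adjusted p = 0.107). ES_Obox5 against ES_Obox6 gave 489 higher and 408 lower calls. The count for ES_Obox3 was 1145 without its unnumbered library, 706 without ES_Obox6 replicate 1 and 1158 without replicate 2, and that for ES_Obox5 was 257 without its replicate 1, 364 without its unnumbered library, 388 without ES_Obox6 replicate 1 and 362 without replicate 2. Over all mESC comparisons, 57 of 144 pairs of a list and a comparison passed camera, 3 with an estimated correlation, and 11 with that correlation after scaling.

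The 9 single libraries had no replicates and were not tested. The genes higher in ES_Obox3 were followed without the Obox, Crxos and Duxf3 genes, which left 941. Of these, 242 were at least 2-fold above the ES_Empty mean in the Obox8 library and 3 at least 2-fold below. The other libraries had between 32 (Obox2) and 64 (Obox4-ps27) such genes above, and ES_Empty replicate 2 had 9 over replicate 1. In the Obox8 library the relative median of these genes was 0.486, against -0.0329 to 0.0728 in the other 8. Their rank among random lists does not set the Obox8 library apart, since 8 of the 9 libraries reached the 95th percentile. The naive pluripotency list was at -0.625 and the early lineage list at 0.872 in the Obox8 library. For 2-cell-stage genes, the Crxos2 and Obox7 libraries stood at the 100th percentile with 5 and 4 members at least 2-fold above ES_Empty, and Zscan4d stood at 3.36 TPM in the Crxos2 library. Zscan4c stood at 1.52 TPM there and at 1.59 TPM in ES_Empty replicate 1. This rank also moves with small differences between controls. ES_Empty replicate 2 over replicate 1 stood at percentile 0 with a median difference of -0.00958. The Obox7 library had the fewest reads, 2.27 on a 1-kb gene at 1 TPM. Genes 4-fold above the ES_Empty mean numbered from 63 (Obox4-ps35) to 235 (Obox7), where ES_Empty replicate 2 had 128 over replicate 1. The genes higher in ES_Obox3 were chosen against the same ES_Empty libraries, which raises such counts in every library.

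**Figure D4:**
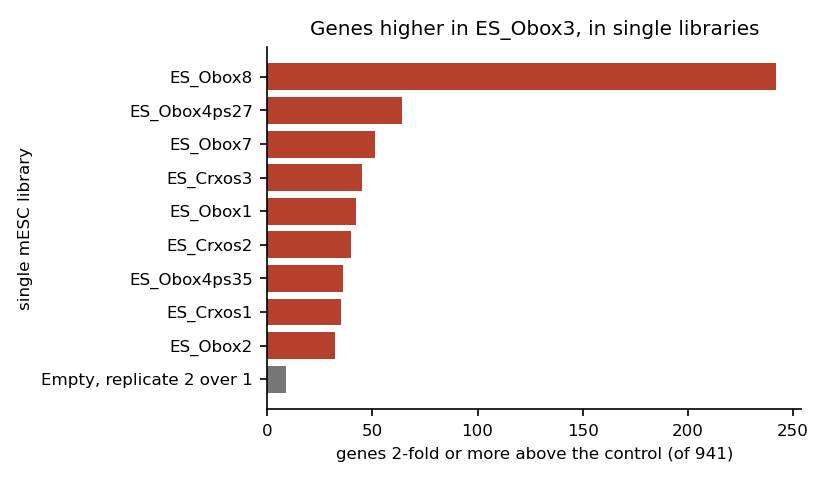
Number of the 941 ES_Obox3-higher genes (x axis) at least 2-fold above the ES_Empty mean in each of the 9 single libraries (y axis). The grey bar is ES_Empty replicate 2 over replicate 1. The Obox8 library has 242 such genes, and the others have 32 to 64.

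SCNT_EGFP_L2C was compared with ICSI_L2C to ask how genome activation in control cloned embryos differs from that in fertilised ones. Genes transcribed at the 2-cell stage were far lower after SCNT. D1Pas1 (chromosome 1, 186967416 to 186970627), an RNA helicase gene, stood at 0.610 ± 0.0418 TPM against 96.6 ± 9.1 (-5.92, SE 0.818, adjusted p = 0.00635). Zscan4a fell from 57.5 ± 13.7 to 0.449 ± 0.185 TPM (-5.32, SE 0.248, adjusted p = 0.000978), Zscan4d from 46.8 ± 26.6 to 0.504 ± 0.261 TPM (-4.88, SE 0.393, adjusted p = 0.00181) and Tcstv3 by a log2 fold change of -4.48 (SE 0.409, adjusted p = 0.00244). Obox3 fell from 71.6 ± 9.98 to 1.84 ± 1.94 TPM (-4.86, SE 0.48, adjusted p = 0.00287) and Obox8 from 148.6 ± 30.3 to 6.38 ± 1.88 TPM (-4.35, SE 0.3, adjusted p = 0.00133). Of 49 measured 2-cell-stage genes 39 were called lower and 0 higher (40 and 0 adjusted over the list alone; relative median -1.89, adjusted p = 3.92e-17, and adjusted p = 0.499 with an estimated correlation), while Zfp352 was not called at -0.54 (adjusted p = 0.232). Of 10 Obox and related homeobox genes 7 were called lower, among them Crxos at -2.46 (relative median -1.36, adjusted p = 0.000549, and adjusted p = 0.499 with an estimated correlation).

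Genes of protein synthesis were also lower. Of 86 ribosomal protein genes 44 were called lower and 0 higher (relative median -0.83, adjusted p = 5.85e-15, and adjusted p = 0.499 with an estimated correlation), against 20 and 1 after scaling. Rpl10l, a retrogene copy of Rpl10, fell by 4.34 (SE 0.222, adjusted p = 0.000978). Of 54 ribosome biogenesis genes 22 were called lower, or 12 after scaling, with Imp3 at -2.46 (SE 0.206, adjusted p = 0.00188; list relative median -0.66, adjusted p = 2.2e-09, and adjusted p = 0.499 with an estimated correlation). Splicing factors had 2 higher and 14 lower calls among 44, or 4 and 8 after scaling, with Snrpa1 at -2.45 (adjusted p = 0.000549, and adjusted p = 0.499 with an estimated correlation). Of 26 naive pluripotency genes 9 were called lower and 1 higher (12 and 1 over the list alone; relative median -0.75, adjusted p = 0.00393, and adjusted p = 0.499 with an estimated correlation), including Tbx3 at -4.25 (SE 0.253, adjusted p = 0.00102) and Fgf4 at -2.79 (SE 0.271, adjusted p = 0.00253). The trophoblast factor Tfap2c fell by 3.47 (SE 0.197, adjusted p = 0.000978) and the p53 target Pmaip1 fell by 4.27 (SE 0.288, adjusted p = 0.00127). Oocyte genes had 10 lower calls among 32 (adjusted p = 0.0109, and adjusted p = 0.639 with an estimated correlation), led by Omt2b at -2.28, and their call was lost without ICSI_L2C replicate 1 (adjusted p = 0.116) and after scaling, with 5 lower calls (adjusted p = 0.185).

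Other genes were higher after SCNT. Rgcc, a cell cycle regulator, rose from 2.17 ± 0.58 to 41.9 ± 4.71 TPM (3.77, SE 0.239, adjusted p = 0.00117), and Ifi30, a lysosomal reductase gene, from 2.66 ± 0.364 to 43.2 ± 4.46 TPM (3.59, SE 0.19, adjusted p = 0.000978). Gadd45g, Hmox1 and the proteasome subunit gene Psma7 rose by 3.49 (SE 0.313), 2.23 (SE 0.218) and 2.14 (SE 0.188). Xist, the RNA that silences an X chromosome, stood at 6.43 ± 6.54 TPM against 0.1 ± 0.0298 and was not called (2.40, adjusted p = 0.0548). Its list had 1 higher and 1 lower call among 8 (3 and 1 over the list alone; relative median 0.81, adjusted p = 0.119). The histone demethylase gene Kdm4d (0.93, adjusted p = 0.0937), Pou5f1 (-0.85, adjusted p = 0.0114) and Sox2 (-1.05, adjusted p = 0.0872) were not called. Cumulus and granulosa cell genes, the markers of the donor cells, had 1 higher and 1 lower call among 12 (2 and 1 over the list alone; relative median 0.43, adjusted p = 0.173). Interferon response genes had 2 higher calls among 5 (adjusted p = 0.117), chromatin modifiers 3 lower, proteasome subunits 2 higher and 2 lower, and DNA replication genes 2 higher and 3 lower. After scaling the calls were 3 higher and 1 lower for chromatin modifiers, 5 and 0 for proteasome subunits and 7 and 1 for DNA replication genes. None of these lists passed camera as deposited or after scaling. The relative median and the test differed in sign for the proteasome list, and the mean and the test for the replication list.

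In all, 877 genes were called higher and 2287 lower, or 27.7% higher, with a median of all genes of -0.20. Median-ratio scaling shifted all genes by 0.32 and gave 1451 higher and 1224 lower calls, or 54.2% higher. Without ICSI_L2C replicate 2 there were 1894 calls and without SCNT_EGFP_L2C replicate 1 there were 1475.

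SCNT_Obox3_L2C was compared with SCNT_EGFP_L2C to ask which genes injected Obox3 mRNA changes in cloned embryos. The MHC class I gene H2-Q6 (chromosome 17, 35424850 to 35430055) stood at 35.5 ± 1.64 TPM against 2.13 ± 1.29 (3.61, SE 0.367, adjusted p = 0.0456). Obox8 rose from 6.38 ± 1.88 to 51.5 ± 16.6 TPM (2.82, SE 0.3, adjusted p = 0.0456), Spic (chromosome 10, 88675269 to 88683023), an ETS family factor, from 5.17 ± 0.106 to 33.8 ± 3.7 TPM (2.49, SE 0.178, adjusted p = 0.0341), and Fam43b rose by 2.49 (SE 0.265, adjusted p = 0.0456). Hes1 (chromosome 16, 30065357 to 30067796), a repressor downstream of Notch, fell from 13.1 ± 3.98 to 1.24 ± 0.437 TPM (-2.64, SE 0.287, adjusted p = 0.0462). The injected gene was not called on Obox3 itself (1.46, adjusted p = 0.198), and Obox3-ps5, chosen after its values were seen, stood at 56.8 and 62.4 TPM against 1.19 and 6.87 TPM with EGFP and 117.7 and 99.5 TPM in ICSI_L2C (3.87 against EGFP, SE 0.555, adjusted p = 0.0718).

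Genes that were low in control SCNT embryos had higher values with Obox3, mostly short of the threshold for a single gene. Of the 2-cell-stage genes 0 were called over all genes and 19 higher adjusted over the list alone (relative median 0.82, adjusted p = 8e-13, and adjusted p = 0.41 with an estimated correlation). Pramel7 stood at 1.45 (adjusted p = 0.0576), Tcstv3 at 2.43 (0.0864), Zscan4d at 2.11 (0.0895), Zscan4c at 1.03 (0.106) and Zfp352 at 0.31. Of the ribosome biogenesis genes 0 were called over all genes and 7 higher over the list alone, with Imp3 at 1.44 (relative median 0.70, adjusted p = 3.52e-21, and adjusted p = 0.41 with an estimated correlation). Ribosomal protein genes had the same counts, with Rpl3 at 1.08 (relative median 0.65, adjusted p = 1.38e-23, and adjusted p = 0.41 with an estimated correlation; adjusted p = 0.0391 with that correlation after scaling). Of the homeobox genes 1 was called, Obox8, and 5 over the list alone (relative median 1.01, adjusted p = 0.00107, and adjusted p = 0.41 with an estimated correlation). Naive pluripotency genes had 1 higher call, Fgf4 at 2.39, and 6 over the list alone (relative median 0.34, adjusted p = 0.0169, and adjusted p = 0.438 with an estimated correlation; adjusted p = 0.0606 without SCNT_Obox3_L2C replicate 1). Splicing factors and proteasome subunits passed upward (adjusted p = 8.62e-05 and 0.00473, and adjusted p = 0.438 and 0.452 with an estimated correlation), the latter not without SCNT_Obox3_L2C replicate 2 (adjusted p = 0.0524). Interferon response genes passed downward (relative median -0.55, adjusted p = 0.0276, and adjusted p = 0.41 with an estimated correlation), a call lost without either SCNT_EGFP_L2C library (adjusted p = 0.171 and 0.184) or SCNT_Obox3_L2C replicate 2 (adjusted p = 0.125), and after scaling (adjusted p = 0.0521). Xist (-0.60, adjusted p = 0.701), Kdm4d (0.28) and Pou5f1 (-0.19) were not called. Across all embryo comparisons, 22 of 51 pairs of a list and a comparison passed camera, 0 with an estimated correlation, and 1 with that correlation after scaling.

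In all, limma called 20 genes higher and 8 lower with Obox3 (71.4% higher), with 3294 genes at an unadjusted p under 0.05, and 94 and 17 (84.7% higher) after scaling. The calls lie at the threshold: 0 were left without ICSI_L2C replicate 1, either SCNT_Obox3_L2C library or SCNT_EGFP_L2C replicate 1, 2 without ICSI_L2C replicate 2 and 5 without SCNT_EGFP_L2C replicate 2, while 427 were made among protein-coding genes alone. H2-Q6, Obox8, Spic, Fam43b, Fgf4 and Hes1 each missed the threshold without any 1 of the 6 libraries, Spic with adjusted p from 0.0566 to 0.188.

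**Figure D5:**
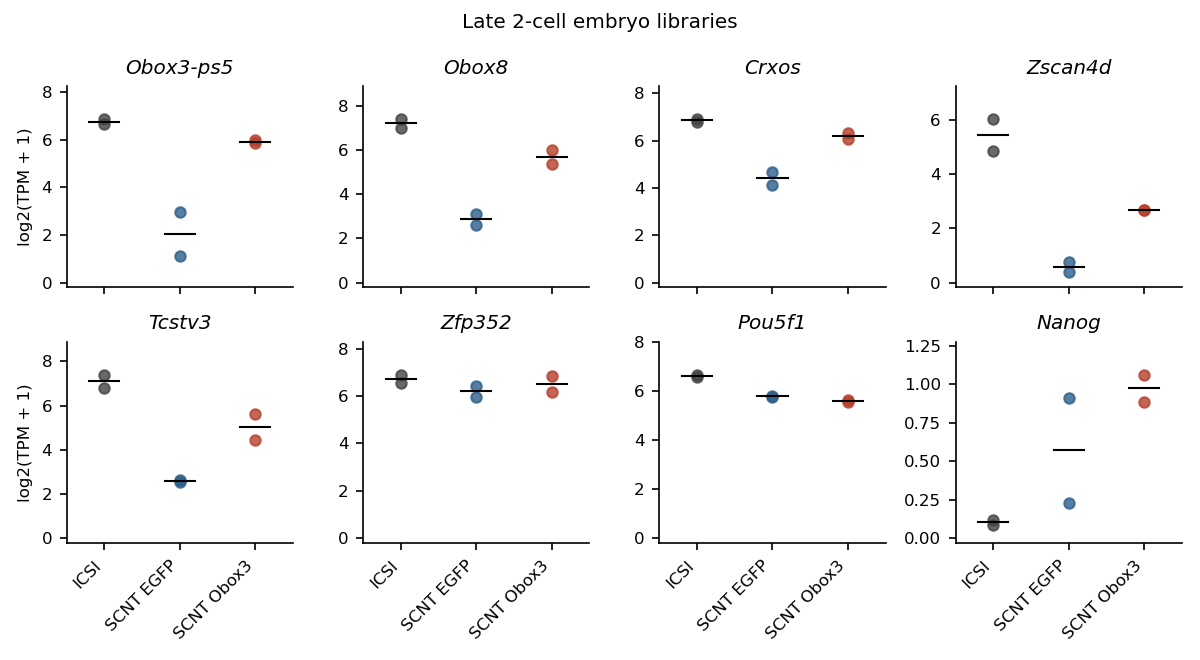
Log2(TPM + 1) (y axis) of Obox3-ps5, Obox8, Crxos, Zscan4d, Tcstv3, Zfp352, Pou5f1 and Nanog in the 3 groups of late 2-cell embryos (x axis); points are libraries and lines are group means. Obox8 stands at 148.6 TPM in ICSI_L2C, 6.38 in SCNT_EGFP_L2C and 51.5 in SCNT_Obox3_L2C.

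The genes called lower in control SCNT embryos were then followed as a set. Of these 2287 genes, 19 were called higher with Obox3 and 0 lower, and 85.2% moved toward ICSI_L2C, with a median change of 0.538 that closed 35.1% of the gap. Unchanged groups simulated with shared SCNT_EGFP_L2C libraries gave a median change of 0.0624, with 59.1% moving toward ICSI_L2C. They closed 3.82% of the gap (at most 4.82%), but hold no deviations that genes share. Of the 877 genes called higher in control SCNT embryos, 84.3% moved toward ICSI_L2C, with a median change of -0.515. After median-ratio scaling 1224 genes were called lower in control SCNT embryos. Of these, 69 were called higher with Obox3 and 0 lower, and 83.1% moved toward ICSI_L2C. As deposited, 932 of the 2287 were still called lower than in ICSI_L2C. The median change was 0.735 without SCNT_EGFP_L2C replicate 2.

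SCNT_Obox3_L2C was compared with ICSI_L2C to measure what difference was left. D1Pas1 had a log2 fold change of -5.18 (SE 0.818, adjusted p = 0.017), a call lost without ICSI_L2C replicate 1 (adjusted p = 0.082) or replicate 2 (adjusted p = 0.0887). Zscan4e fell by 4.92 (SE 0.244, adjusted p = 0.00388), Zscan4b fell by 4.57 (SE 0.266, adjusted p = 0.00441) and Zscan4c fell by 3.19 (SE 0.229, adjusted p = 0.00479). Fez1 rose by 3.19 (SE 0.213, adjusted p = 0.00441) and Lypd5 rose by 3.02 (SE 0.313, adjusted p = 0.00743). Of the 2-cell-stage genes 25 were called lower and 0 higher, or 16 and 0 after scaling (27 and 0 over the list alone; relative median -1.11, adjusted p = 4.81e-09, and adjusted p = 0.69 with an estimated correlation), and of the oocyte genes 8 were called lower, or 5 after scaling (adjusted p = 0.00033, and adjusted p = 0.69 with an estimated correlation). The homeobox list had 4 lower calls (adjusted p = 0.0324, and adjusted p = 0.69 with an estimated correlation; adjusted p = 0.0651 without ICSI_L2C replicate 1 and 0.108 without SCNT_Obox3_L2C replicate 1). Proteasome subunits had 3 higher calls (adjusted p = 0.0127, and adjusted p = 0.69 with an estimated correlation) and ribosomal proteins 2 higher and 5 lower (adjusted p = 0.0127, and adjusted p = 0.759 with an estimated correlation; adjusted p = 0.0561 without SCNT_Obox3_L2C replicate 1, and 0.363 after scaling, with 2 higher and 2 lower). Xist had a log2 fold change of 1.80 (adjusted p = 0.148) and Zfp352 of -0.23. In all, 511 genes were called higher and 1152 lower (30.7% higher), and 783 and 624 (55.7% higher) after scaling, with a median of all genes of -0.22 before it. The count was 452 without ICSI_L2C replicate 1, 565 without replicate 2, 605 without SCNT_Obox3_L2C replicate 1 and 404 without replicate 2.

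Genes that responded in mESCs were tested in the embryos, which come from other libraries and another table. Without the Obox genes and Duxf3, 942 genes were called higher in ES_Obox3, and 825 of them were measured. With Obox3 mRNA their relative median was 0.461 against SCNT_EGFP_L2C, with 7 higher and 1 lower calls (adjusted p = 6.74e-13, and adjusted p = 0.262 with an estimated correlation), after -0.409 in SCNT_EGFP_L2C against ICSI_L2C, with 45 higher and 241 lower calls (adjusted p = 0.00026, and adjusted p = 0.473 with an estimated correlation). Against ICSI_L2C the genes stood at 0.0222 with Obox3 (adjusted p = 0.753). The 1951 measured genes lower in ES_Obox3 had a relative median of -0.174 with Obox3 mRNA (adjusted p = 1.33e-06, and adjusted p = 0.262 with an estimated correlation). The rise was not particular to the ES_Obox3 list. The 842 measured genes higher in ES_Obox5, many of them shared with that list, stood at 0.455 (limma camera adjusted p = 1.35e-12). The 357 higher in ES_Obox6 stood at 0.208 (limma camera adjusted p = 0.000115). Both had adjusted p = 0.262 with an estimated correlation. For the 573 measured genes higher in ES_Dux, the relative median was -0.827 in SCNT_EGFP_L2C against ICSI_L2C, with 244 lower calls (adjusted p = 3.75e-09, and adjusted p = 0.473 with an estimated correlation), and 0.192 with Obox3 against EGFP (adjusted p = 0.000903, and adjusted p = 0.459 with an estimated correlation). That value was 0.086 (limma's camera, unadjusted p = 0.0588) without SCNT_EGFP_L2C replicate 1, and the difference between the ES_Obox3 and ES_Dux lists was not tested. The genes called lower in SCNT_EGFP_L2C and higher in ES_Obox3 numbered 241 and closed 51.2% of the gap to ICSI_L2C, and the other 2046 closed 33.0%. Of 14770 genes tested in both tables, 9 were called higher with Obox3 in both, where independent lists would share 0.85. This overlap rests on 15 higher calls in embryos among the 14770 genes. The embryo calls lie at the threshold, and most were lost without any 1 of the 6 libraries. Among the 9 shared genes were Obox8 and H2-Q6, and Hes1 was the 1 gene called lower in both (0.92 if independent). In ES_Obox3, Obox8 was near the floor, at 1.61 and 1.39 TPM. Exoc3l2, Larp1b, Npl and Obox3-ps4 were also in the higher set, chosen after their values were seen. Obox3-ps4 is another copy of Obox3, so reads of the introduced RNA cannot be told from its own.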

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

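The rescaling without the most abundant genes, and in the embryos the comparison with simulated groups and the median-ratio test of the gap, were chosen after the result was seen.

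For 10 gene lists and 1 gene, values with Obox3 lay on one side in both mESC libraries and on the other in both SCNT embryo libraries. Naive pluripotency genes stood at -0.63 relative to all genes in ES_Obox3 (libraries -0.72 and -0.55) and at 0.38 in SCNT_Obox3_L2C (0.21 and 0.56). Proteasome subunits stood at -0.18 (-0.22 and -0.14) and 0.33 (0.32 and 0.35). Their mESC call was lost with an estimated correlation, without each of 2 libraries and after scaling (limma camera adjusted p = 0.827). Stress and immediate early genes, which passed camera in neither system, stood at 0.23 (0.18 and 0.28) and -0.27 (-0.37 and -0.17). In the same order, oocyte genes stood at 0.97 (0.83 and 1.10) and -0.07 (-0.13 and -0.01), and trophoblast genes at -0.14 (-0.23 and -0.05) and 0.64 (0.66 and 0.62). Splicing factors stood at -0.13 (-0.07 and -0.20) and 0.33 (0.31 and 0.34), and ribosomal proteins at -0.07 (-0.05 and -0.10) and 0.64 (0.65 and 0.62). Chromatin modifiers stood at -0.11 (-0.04 and -0.19) and 0.10 (0.06 and 0.14), p53 targets at -0.29 (-0.28 and -0.31) and 0.07 (0.03 and 0.11), and DNA replication genes at -0.12 (-0.04 and -0.20) and 0.07 (0.01 and 0.12). Each of these 7 had at least 1 library within 0.1 of 0. Gm25406 had a log2 fold change of 2.61 in ES_Obox3 against ES_Empty and -4.03 in SCNT_Obox3_L2C against SCNT_EGFP_L2C. The difference between the 2 systems was not tested for any of these, and the tables were normalised separately.

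More genes were lower than higher in ES_Obox3 and ES_Dux against ES_Empty. The 10 most abundant genes took 64.3 and 73.8% of the TPM in ES_Obox3 and 72.0 and 69.4% in ES_Dux, against 54.4 and 58.8% in ES_Empty. After TPM were rescaled without them, the median of all genes was -0.058 in ES_Obox3 (-0.095 to 0 over pairs of libraries), with 1516 higher and 1151 lower calls, so these genes may account for the excess there, but it was -0.61 in ES_Dux (-0.619 to -0.582), with 965 and 4180, so they are not its whole cause. Fewer reads would lose low genes and spare abundant ones. Yet 1199 genes with a mean of at least 50 TPM had medians of -0.572 in ES_Obox3 (-0.932 to -0.215) and -0.958 in ES_Dux (-1.162 to -0.784). Fewer reads are therefore not the whole cause. The rise of the 10 most abundant genes lowers these medians as well, so they cannot decide whether fewer reads played a part. A 1-kb gene at 1 TPM rested on 4.27 and 7.37 reads in ES_Obox3 and 7.08 and 5.0 in ES_Dux, against 3.72 and 4.88 in ES_Empty. A change in the amount of RNA per cell stays open and was not tested, since no spike-in values were used here.

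Genes low in control SCNT embryos moved toward ICSI_L2C with Obox3 mRNA. Noise drawn separately for each gene in shared SCNT_EGFP_L2C libraries does not account for it. The median share of the gap closed was 35.1%, against at most 4.82% in simulated unchanged groups. Deviations that many genes share in the SCNT_EGFP_L2C libraries were not simulated, so these libraries stay open as a cause. A shift of the TPM scale does not account for it, since the share was 34.1% after median-ratio scaling, against at most 5.34%. A general difference between the embryos, not tied to genes that Obox3 raised in mESCs, may account for part of it. The 2046 genes not called higher in ES_Obox3 closed 33.0% of the gap (31.0 to 34.7% when genes were resampled). That range takes genes as independent and leaves out the spread between libraries. The 241 called higher in ES_Obox3 closed 51.2%, and the difference between the sets was not tested. An effect of Obox3 on these genes stays open and was not tested.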

How the results depend on the processing

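Rescaling without the 10 most abundant genes, median-ratio scaling together with an estimated correlation, the fits of protein-coding genes alone, the block, rescaling and left-out libraries for the shift in SCNT embryos, the left-out libraries for the overlap, and the list means and left-out ES_Empty libraries for single libraries were chosen after the data were seen.

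Apart from left-out libraries, 87 counts of called genes stayed within 1.5 times and 38 moved further. Of the list results 1845 kept their direction and side of the threshold, 244 lost the threshold, 67 newly passed and 31 changed the direction of camera, and of the named genes 7272, 466 and 162, with 6 of changed sign. With a library left out, 65 counts stayed and 33 moved, and 1643 list and 6411 gene results held. Values near 1 TPM rest on 2.27 to 7.37 reads for a 1-kb gene in mESCs and 5.06 to 13.9 in embryos. No comparison with siRNA against Obox3 was run, since those samples had no values here. For the changes below, the cause was not tested unless stated.

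Without a minimum fold change, a looser criterion, the calls numbered 6377 in ES_Obox3 against ES_Empty and 2844 against ES_Obox6. A pseudocount of 5, which shrinks the changes of low genes, left 1128 in ES_Obox3, 3453 in ES_Dux, 671 in ES_Obox5 and 325 in ES_Obox6 against ES_Empty, and 1815, 538 and 331 in ES_Obox3 against ES_Dux, ES_Obox3 against ES_Obox6 and ES_Obox5 against ES_Obox6. In embryos it left 1570 in SCNT_EGFP_L2C against ICSI_L2C, 8 in SCNT_Obox3_L2C against SCNT_EGFP_L2C and 796 against ICSI_L2C. A pseudocount of 0.1 gave 7 in ES_Obox3 against ES_Obox5. With a filter at 5 TPM, which tests fewer genes, there were 2451 in ES_Obox3 against ES_Empty, 2 against ES_Obox5, 273 in SCNT_Obox3_L2C against SCNT_EGFP_L2C and 35 mESC list calls. With no filter there were 567 in ES_Obox6 against ES_Empty, 1064 and 582 in ES_Obox3 and ES_Obox5 against ES_Obox6, and 0 and 718 in SCNT_Obox3_L2C against SCNT_EGFP_L2C and ICSI_L2C.

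Median-ratio scaling gave 2320 in ES_Obox3 and 1876 in ES_Dux against ES_Empty, 20 in ES_Obox3 against ES_Obox5 and 111 in SCNT_Obox3_L2C against SCNT_EGFP_L2C. Quantile normalization gave 2328, 1779 and 18 for the mESC comparisons in that order. Rescaling without the 10 most abundant genes gave 5145 in ES_Dux and 20 in ES_Obox3 against ES_Obox5. Fitting only the groups compared gave 576 in ES_Obox6 against ES_Empty, 352 in ES_Obox3 against ES_Obox5 and 0 in SCNT_Obox3_L2C against SCNT_EGFP_L2C. For ES_Obox3 against ES_Obox5 and SCNT_Obox3_L2C against SCNT_EGFP_L2C, plain moderation gave 28 and 3, and protein-coding genes alone gave 104 and 427. With an estimated correlation 3 mESC and 0 embryo list calls were left, and in embryos the genes higher in ES_Obox3 (0.461, unadjusted limma camera p = 0.127), lower in ES_Obox3 (-0.174, 0.108) and higher in ES_Dux (0.192, 0.402) no longer passed. With that correlation after median-ratio scaling, 11 mESC and 1 embryo list calls were left. Of the response lists, called anew after scaling, the genes higher in ES_Obox3 passed at 0.413 (limma camera, unadjusted p = 0.00979), and those lower in ES_Obox3 (-0.237, 0.0678) and higher in ES_Dux (0.221, 0.225) did not. With a pseudocount of 5 the genes lower in ES_Dux passed at 0.083 (limma camera, unadjusted p = 0.0042). ES_Obox3 and ES_Dux shared 300 higher calls with a pseudocount of 0.1, 33 with 5 and 285 after scaling, and 556 lower calls with a pseudocount of 5, 142 after scaling and 179 with quantile normalization. Single libraries at or above the 95th percentile of random lists went from 2 to 4 for 2-cell-stage genes with list means, from 8 to 5 for genes higher in ES_Obox3 after scaling, and from 0 to 9 for genes higher in ES_Dux with list means.

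The replicate numbers did not pair the libraries. The deviations of same-numbered libraries had a correlation of 0.046 between ES_Empty and ES_Obox6, 0.046 between ICSI_L2C and SCNT_Obox3_L2C, 0.014 between ICSI_L2C and SCNT_EGFP_L2C and 0.067 between the SCNT groups. With the replicate number as a block there were 841 calls in ES_Obox6 against ES_Empty, 3065 in SCNT_EGFP_L2C against ICSI_L2C, 0 in SCNT_Obox3_L2C against SCNT_EGFP_L2C and 1566 against ICSI_L2C, 20 embryo list calls and 9 in ES_Obox6, relative medians of 0.461, -0.174, 0.192 and 0.017 for the response lists and a shift of 0.546. For comparisons that include ES_Dux, ES_Obox3 or ES_Obox5, no paired analysis was run. The second library of these groups carries the number 3 in its column name, which the labels do not have. Whether the libraries numbered 3 deviate together was not examined.

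With each library left out in turn, the calls against ES_Empty ranged from 2234 to 4902 in ES_Obox3, 8593 to 10024 in ES_Dux, 1074 to 2218 in ES_Obox5 and 325 to 1016 in ES_Obox6. They ranged from 3180 to 6353 in ES_Obox3 against ES_Dux, 1 to 14 against ES_Obox5 and 706 to 2567 against ES_Obox6, and from 257 to 1003 in ES_Obox5 against ES_Obox6. In embryos they ranged from 1475 to 3070 in SCNT_EGFP_L2C against ICSI_L2C, 404 to 1523 in SCNT_Obox3_L2C against ICSI_L2C and 0 to 5 against SCNT_EGFP_L2C. List calls ranged from 50 to 68 in mESCs and 19 to 21 in embryos. Response lists in embryos ranged from 0.355 to 0.534 and -0.211 to -0.119 for genes higher and lower in ES_Obox3, and 0.086 to 0.389 and 0 to 0.051 for ES_Dux. The shift in SCNT embryos ranged from 0.526 to 0.735. ES_Obox3 and ES_Dux shared 118 to 198 higher and 1276 to 3416 lower calls, with correlations of 0.415 to 0.537. Single libraries at or above the 95th percentile for genes higher in ES_Obox3 numbered 5 to 6.

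Under another scaling some called genes changed sign, and some lists changed the direction of camera. The list values below are relative medians, which need not change sign with the test. With median-ratio scaling, ES_Dux against ES_Empty had Psmd11 at 0.173, Psmd12 at 0.077, Rpl7l1 at 0.105, Rps27 at 0.35 and Khdc3 at 0.08, and its ribosome biogenesis, proteasome, splicing and ribosomal lists at 0.128, 0.552, 0.224 and 0.776. The same lists stood at 0.232, -0.02, 0.016 and 0.075 in ES_Obox3 against ES_Empty, the proteasome list at -0.413 against ES_Dux, and the ribosome biogenesis and ribosomal lists at 0.097 and 0.034 against ES_Obox5. With quantile normalization, Khdc3 stood at 0.056 and the proteasome list at 0.234 in ES_Dux, the ribosomal list at 0.067 in ES_Obox3 against ES_Empty and -0.006 in SCNT_Obox3_L2C against ICSI_L2C, and ribosome biogenesis and ribosomal lists at 0.104 and 0.09 in ES_Obox3 against ES_Obox5. Rescaled without the 10 most abundant genes, ribosome biogenesis and ribosomal lists stood at 0.212 and 0.053 in ES_Obox3 and the ribosomal list at 0.482 in ES_Dux. Against ES_Obox5 the ribosome biogenesis, proteasome, splicing and ribosomal lists stood at 0.123, 0.084, 0.078 and 0.059 in ES_Obox3, and against ES_Obox6 the proteasome list at 0.165.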

Other observations

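The test for Obox3 plasmid in the Obox8 library and the choice of the region on chromosome 12 were made after the result was seen.

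Genes of an imprinted region on chromosome 12, from Dlk1 to Dio3 (109452485 to 110281097, 829 kb, 77 genes), included many lower calls in ES_Obox3 and ES_Obox5. In ES_Obox3 against ES_Empty 23 were called lower and 0 higher (15 lower after median-ratio scaling). In ES_Dux 29 were lower and 1 higher (8 lower after scaling), in ES_Obox5 16 lower (14 after scaling) and in ES_Obox6 1 lower and 2 higher. Of all 20355 genes tested, 2770 were lower in ES_Obox3 (835 after scaling) and 9029 in ES_Dux (477 after scaling). In ES_Obox5 1114 were lower (534 after scaling) and in ES_Obox6 406 (243 after scaling). The medians over the region were -2.08, -1.66, -1.66 and -0.45, and -1.68, -0.94, -1.37 and -0.21 after scaling. They were the same, -1.655, in ES_Dux and ES_Obox5 as deposited. On a small RNA gene such a value can come from few reads in ES_Empty and none in the other group. The medians may thus lie near the floor, and at -2.08 in ES_Obox3 only 23 of the 77 genes were called. In ES_Obox3 the noncoding RNA gene Meg3 fell by 2.31 (SE 0.207, limma adjusted p = 0.000248), and Rtl1, Rian and Mirg fell by 2.30, 2.10 and 2.06, all called after scaling too. Meg3 fell by 1.75 in ES_Obox5, called under both scales, and by 1.62 in ES_Dux, where it was not called after scaling. Dio3, an enzyme gene that inactivates thyroid hormone, stood at 1.45 in ES_Obox6 (limma adjusted p = 0.0211). Many of the 77 genes are small RNAs that lie within longer transcripts, so the calls are not independent, and no test of the region was run.

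The Obox8 library carried genes that were higher in ES_Obox3. The ES_Empty libraries shared by both comparisons do not account for it: with the mean of the other 8 single libraries as control, the relative median of these genes was 0.395 in the Obox8 library and -0.13 to 0.006 in the others, and 180 of 942 genes were at least 2-fold higher, against 14 to 33. Obox3 plasmid in that library is also argued against, since Obox3-ps5 stood at 0% of its lower ES_Obox3 value there (0 to 0.167% in the other single libraries). A response to Obox8 that overlaps the response to Obox3 may stay as a hypothesis, but it rests on 1 library and was not tested.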
